A study of Jatropha curcas with 10 samples.

How the data were processed

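RNA sequencing was carried out on total RNA from inflorescence meristems of Jatropha curcas, an oilseed shrub, collected at 5 times after exogenous treatment with GA3 (gibberellic acid, a plant growth hormone); the labels do not give the mode or dose of the treatment. Each of the 10 libraries has 1 deposited table with a value for each of 28447 gene IDs, of which 27172 are locus tags starting with JCGZ and 1275 are other IDs, such as Novel00683. The unit is not written in the tables; per the file headers, they hold only the gene ID and the library title. The values deposited by the authors were read as RPKM (reads scaled to gene length and to the reads counted in the library) because they behave as whole reads divided by gene length and library depth; whether reads or read pairs were counted is not given in the sources used here. Per the submitters' processing notes, Bowtie 0.12.2 and the build mm8 were used, with no role stated. The build mm8 is a mouse genome, while the gene IDs are those of a Jatropha annotation, and the genome aligned to is not otherwise given in the sources used here. The counting tool, the annotation release and any filter are not given in the sources used here.

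The reads behind the RPKM values were recovered from the values themselves. The commonest ratio of a gene's values between libraries gave the relative value of 1 read, and the smallest set of whole numbers in the ratios of each gene gave its reads. In all, 99.98% of the 203696 values above 0 came out within 0.01 of a whole read number, and reads were recovered for every gene. The library denominator was then the number that made the gene lengths whole, and 99.98% of 22085 lengths were whole within 0.02 bases. Of the JCGZ lengths, 99.9% were multiples of 3, so they are coding lengths without untranslated regions, with a median of 1062 bases. Of the lengths of the other IDs, 34.0% were multiples of 3. On 4000 simulated genes, 99.9% of those with 10 or more reads were recovered exactly. The recovered depth was 15932450 to 24445093 reads per library, 99.96% to 99.97% of the denominators. At a gene length of 1 kb, 3 reads correspond to 0.123 to 0.188 RPKM, and the limits set by reads cover counting error only. The 6362 genes at 0 in every library were not tested.

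The 10 libraries were grouped by the time in their labels (0, 6, 12, 24 and 48 h, 2 libraries each). The labels give no untreated plants at the later times, so treatment, time since treatment and time of day change together. Nothing in the labels says that the 2 libraries of a time came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. To look for repeated deposits of 1 library, the libraries of a time were compared: 0 values above 0 were identical, and their read counts differed by more than counting noise (chi-square per degree of freedom of 57.0 to 169.8). This does not show that they came from separate plants or RNA pools.

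Because the values were read as RPKM, changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend and robust moderation). The test used log2(RPKM + 1) of the 17403 genes with a mean of at least 1 RPKM over the 10 libraries. All 10 libraries entered 1 model with time as a factor, so that all times share an estimate of the spread. The 4 comparisons against 0 h, 4 comparisons between treated times and an F-test of change over any of the times were fixed before the data were examined. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Data were simulated on 17165 genes with the spread of these libraries, to which counting noise was added although that spread already holds it. In them 200 genes changed at 12 h, all drawn from genes with at least 100 reads at 0 h, so lower genes were not covered. The same test called 51 of 100 genes changed 4-fold and 0 of 100 changed 2-fold, and 1 unchanged gene. The choice of robust moderation as the main setting was settled after counts without it had been seen; it was named before the data were examined, as the setting whose alternative is non-robust moderation. The design set count-based packages for deposited counts and limma for values such as RPKM, so count-based packages were not used. The recovered reads were tested only in an added limma-voom fit.

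The design fixed 30 gene lists as patterns on product descriptions (gibberellin metabolism and signalling, clock, flowering, meristem, cell wall, hormone and marker lists). They could not be run. Of the 28447 IDs, 0 matched the supplied RefSeq table of 28617 genes, and the deposited tables do not pair IDs with names. Genes are therefore given by ID, without names or genome positions. The rule for named genes, fixed before the data were examined, then allowed at most 2 IDs that rose and 2 that fell per comparison with 0 h. They are the largest fitted changes among genes with an adjusted p under 0.05, a mean of at least 5 RPKM and both libraries of the time on the same side of both 0 h libraries.

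The libraries carry the numbers 1 and 2 at every time. Whether the numbers pair libraries was checked before calls were compared, from the correlation over genes of the differences between number 1 and number 2. Between the 4 treated times these correlations were 0.54 to 0.70, so the numbers were taken to pair the treated libraries. With 0 h they were -0.32 to -0.14, so they do not pair the 0 h libraries with the others. The alternatives were median-of-ratios and upper-quartile scaling, pseudocounts of 0.1 and 5, no filter or a mean of at least 5 RPKM, non-robust moderation, the replicate number as a block, a 2-fold minimum, fits to the 4 libraries of a comparison, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, library weights, a spline correction for coding length in each library (5 degrees of freedom), and that correction or the block among the 8 treated libraries. Overlaps between comparisons that share libraries were set against 50 simulated data sets with no change. Recovery used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.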

Results

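The series followed the transcriptome of Jatropha curcas inflorescence meristems, the growing tips that form the flowers, after treatment with the gibberellin GA3. Meristems were sampled at 0, 6, 12, 24 and 48 h, with 2 libraries per time. The recovered depth was 17922243 and 19154863 reads at 0 h, 15932450 and 17920243 at 6 h, 20631916 and 19089840 at 12 h, 18111829 and 24445093 at 24 h, and 18350382 and 17974532 at 48 h. Between 20166 and 20599 genes had reads in each library. The most abundant transcript was JCGZ_00661 (coding length 360 bases), with a mean of 11266 RPKM and a range of 5774 to 17841 over the 10 libraries, and Novel00683 and JCGZ_18885 followed with means of 7512 and 7108 RPKM.

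Most of the variation between libraries lay along 2 directions. The first principal component (37.0% of the variance of log2(RPKM + 1)) separated number 1 from number 2 at each treated time, with scores of 24.8 to 59.1 for number 1 and -62.5 to -21.3 for number 2. The second component (26.3%) separated the 4 libraries of 6 and 12 h, at -61.9 to -28.5, from the 6 libraries of 0, 24 and 48 h, at 8.79 to 47.1. The 0 h libraries were closest to each other (Pearson r over genes of 0.97), whereas library 1 of 6 h was closest to library 1 of 12 h (r = 0.97) and library 1 of 24 h to library 1 of 48 h (r = 0.97). Among the libraries of number 2, those of 6 h and 12 h were closest to each other (r = 0.946), that of 48 h was closest to that of 24 h (r = 0.962), and that of 24 h was closest to that of 0 h (r = 0.969).

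**Figure D1:**
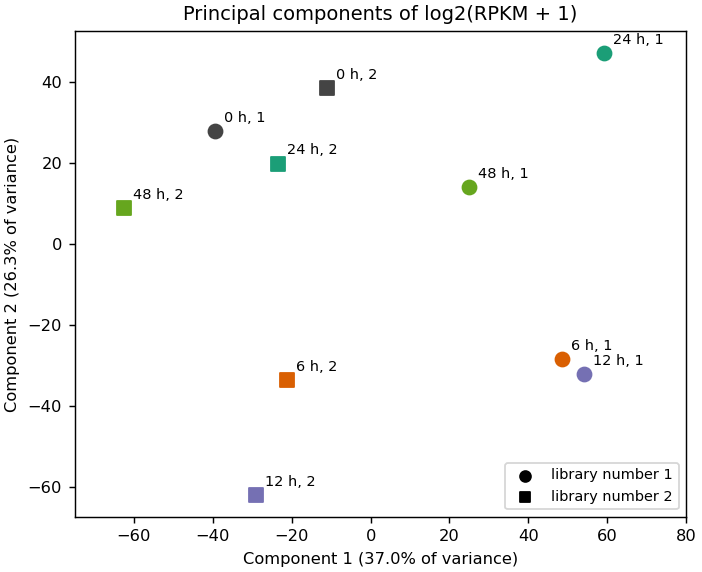
Scores of the 10 libraries on the first and second principal components of log2(RPKM + 1), in arbitrary units, coloured by time, with circles for library number 1 and squares for number 2. The 6 and 12 h libraries lie below 0 on the second component and the 0, 24 and 48 h libraries above 0, and number 1 lies to the right of number 2 at each treated time but not at 0 h.

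The libraries of 1 time also differed by gene length. At 12 h the median difference of library 1 minus library 2 was 0.47 (log2) in the shortest of 10 length classes (median 333 bases) and -0.96 in the longest (median 2992.5 bases). The same trend held at 6, 24 and 48 h, with Spearman correlations over genes of -0.36, -0.48 and -0.49 between difference and length, against -0.57 at 12 h. At 0 h it had the opposite sign (0.41). Genes are not independent replicates, so no p is attached to these values. The standard deviation of the replicate difference was 0.50 at 0 h and 0.70 to 0.76 at the treated times.

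**Figure D2:**
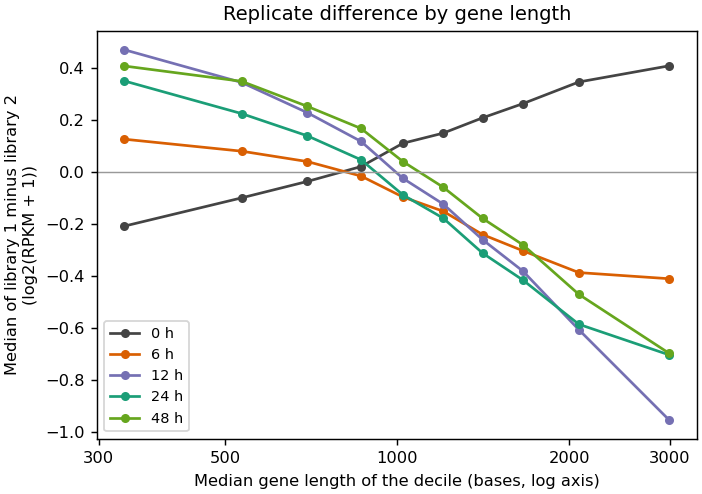
Median difference between library 1 and library 2 of each time (log2(RPKM + 1)) in 10 classes of gene length, plotted at the median length of each class in bases on a log axis. The difference falls with length at 6, 12, 24 and 48 h and rises with length at 0 h.

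The first comparison asked which transcripts had changed 6 h after GA3. At 6 h, 84 genes rose and 113 fell against 0 h among 17403 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The rising genes changed by a median of 2.30 (log2) and the falling genes by -2.23, and each of the 197 changed at least 2-fold. Together the 84 rising genes took 0.194% ± 0.020 of all reads at 0 h and 1.06% ± 0.059 at 6 h, and the 113 falling genes went from 1.57% ± 0.160 to 0.238% ± 0.020 (SD, n = 2 each). JCGZ_08534 (510 coding bases) showed the largest increase, from 6.54 ± 1.73 RPKM at 0 h to 644 ± 120 at 6 h (SD, n = 2). Its fitted change was 6.43 ± 0.61 (log2, SE; limma adjusted p = 0.00397). JCGZ_01274 (387 bases) rose from 1.47 ± 0.17 to 218.9 ± 92.3 RPKM, from 11 and 10 reads to 1753 and 1066 reads. JCGZ_14173 (2298 bases) fell from 375.5 ± 28.9 to 10.4 ± 7.5 RPKM, a change of -5.23 ± 0.43 (log2, SE; limma adjusted p = 0.00185). JCGZ_24966 (270 bases) fell from 297 ± 125 to 7.36 ± 0.77 RPKM (limma adjusted p = 0.0161, and 0.0507 by voom on the recovered reads). The count of 197 rested on every library of the comparison: it was 34 without 0 h library 1, 17 without 0 h library 2, 23 without 6 h library 1 and 39 without 6 h library 2. It was also 128 without either 48 h library. The share of falling genes was 57.4% with all libraries and 30.8% to 39.1% without a library of 0 or 6 h, so the data do not fix whether more genes rose or fell at 6 h. Without 0 h library 1 or 2 the limma adjusted p of JCGZ_24966 was 0.169 and 0.0986, and without 6 h library 1 or 2 it was 0.117 and 0.116 (0.000105 to 0.169 over 24 alternatives). That of JCGZ_08534 was 0.0641 without 0 h library 2 and 0.0561 without 6 h library 1 (1.95e-05 to 0.0641 over 24 alternatives).

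At 12 h the falling genes outnumbered the rising ones. Against 0 h, 225 genes fell and 42 rose (limma, adjusted p under 0.05), with median changes of -2.55 and 2.13 (log2), and all 267 changed at least 2-fold. Among those that fell, 69 started at 100 RPKM or more at 0 h and 81 fell at least 8-fold, whereas 7 of the rising genes reached 100 RPKM and 7 rose at least 8-fold. The 225 falling genes took 4.43% ± 0.034 of all reads at 0 h, 1.67% ± 0.078 at 6 h and 0.446% ± 0.028 at 12 h (SD, n = 2 each). JCGZ_02232 (585 coding bases) fell from 2940 ± 731 RPKM at 0 h through 162.6 ± 86.7 at 6 h to 4.63 ± 0.92 at 12 h, a change of -9.02 ± 0.73 at 12 h (log2, SE; limma adjusted p = 0.00166). JCGZ_02380 (366 bases) fell from 541.5 ± 56.3 to 3.88 ± 1.44 RPKM, a change of -6.82 ± 0.52 (limma adjusted p = 0.00148). JCGZ_26846 (1275 bases) rose from 0.769 ± 0.335 to 51.4 ± 2.0 RPKM, from 23 and 13 reads to 1390 and 1216 reads (limma adjusted p = 0.000834). JCGZ_10281 (237 bases) rose from 1.01 ± 0.43 RPKM (3 and 6 reads) to 53.7 ± 35.6 RPKM (386 and 129 reads), with a limma adjusted p of 0.0159. By voom on the recovered reads its adjusted p was 0.0783, above the threshold. The call was also lost without 0 h library 1, 0 h library 2 or 12 h library 1, with changes of 4.39, 4.83 and 3.89 (log2) against 4.61 with all libraries. The count of 267 was 35 and 53 without 0 h library 1 or 2, and 95 and 93 without 12 h library 1 or 2, and 87.1% to 92.5% of the calls were falls in those 4 fits. The number of rising genes moved from 42 to 80 (181 fell, 69.3% of the calls) in a fit to the 4 libraries of 0 h and 12 h, and to 200 (527 fell, 72.5%) with the coding length correction and the replicate block.

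**Figure D3:**
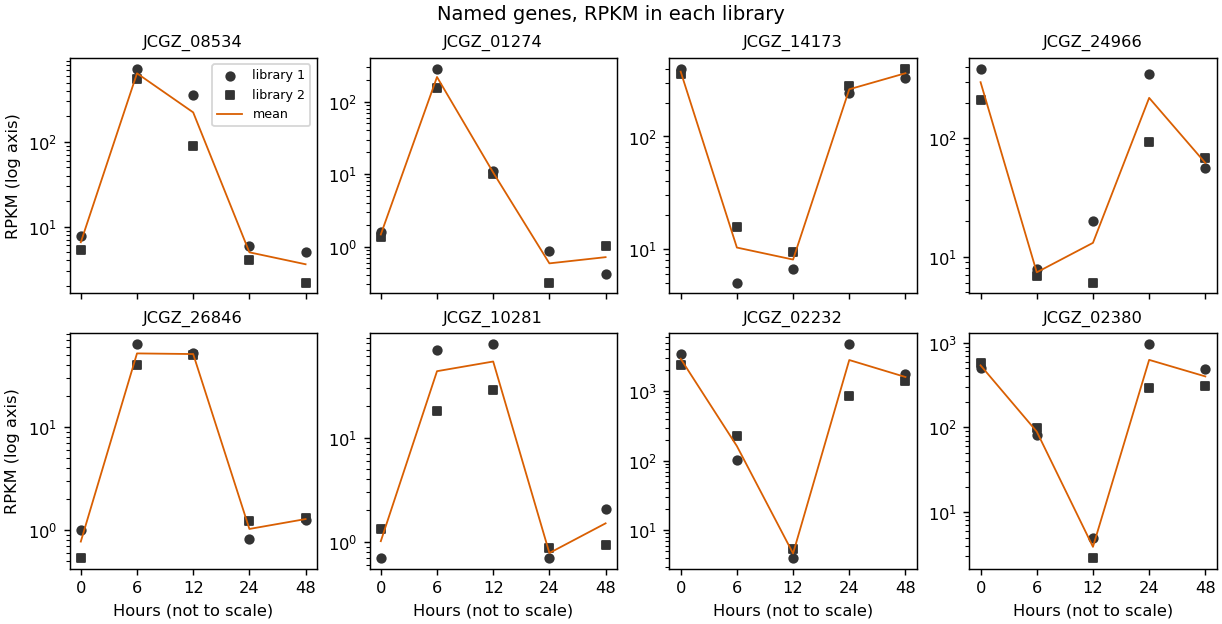
RPKM of the 8 named genes in each library on log axes (circles, library 1; squares, library 2; line, mean of the 2 libraries) against hours after GA3, not to scale. All 8 return towards the 0 h level by 24 h, JCGZ_02232 for example from a mean of 4.63 RPKM at 12 h to 4782 and 858 RPKM in the 24 h libraries.

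Part of the genes called at 6 h were also called at 12 h. Of the 84 and 42 genes that rose at 6 h and 12 h, 32 rose at both, and of the 113 and 225 that fell, 88 fell at both, while 0 went in opposite directions. Independent lists of these sizes would share 0.203 rising and 1.46 falling genes, a value that leaves out the shared 0 h libraries. In 50 simulated data sets with no change at any time, the lists shared 0 genes. All libraries were drawn anew there, those of 0 h served both comparisons, and the fit used non-robust moderation. Such data give hardly any calls, so this 0 sets no bound on the overlap of called genes. The log2 changes at 6 and 12 h correlated over genes with r = 0.773 (0.501 in simulated unchanged groups) and had a covariance of 0.367 (0.0993 simulated), a difference of 0.268. For the other pairs of times the covariance exceeded the simulated one by 0.0397 to 0.123, while the correlation was 0.441 to 0.616 and lay below the simulated value for 6 h with 24 h (0.495 against 0.501) and 6 h with 48 h (0.441 against 0.503). The share of genes with the same sign was 78.6% for 6 h with 12 h (66.7% simulated) and below the simulated share in the other pairs (59.6% to 64.4%) except 12 h with 48 h (69.1% against 66.6%). The simulated data held no shift of all genes and no length trend. In the data the median change of all genes was -0.15 at 24 h. Changes correlated with coding length at -0.26 at 24 h and 0.33 at 48 h (Spearman). A share below the simulated one therefore does not show that the changes of single genes disagreed. The simulated libraries were drawn independently, whereas the library numbers paired the treated ones. They were also given 1 spread for all times, whereas the standard deviation of the replicate difference was 0.50 at 0 h and 0.70 to 0.76 at the treated times. With a smaller spread at 0 h, shared libraries would add less correlation and covariance than simulated. A correlation below the simulated value therefore does not place a pair of times below the level of no change. Both comparisons use the same 2 libraries of 0 h, so part of the excess of shared calls over independent lists may come from them. An overlap with a different 0 h library for each comparison was not computed. The simulated covariance already contains shared 0 h libraries, but with 1 spread for all times. The overlap of 120 was 8 to 119 when single libraries were left out, lowest without 0 h library 2 (8) and 0 h library 1 (11), and it was 19 and 31 without 6 h library 1 or 2 and 49 and 57 without 12 h library 1 or 2. Without 48 h library 1 or 2 it was 73 and 74.

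At 24 h and 48 h no gene passed the threshold against 0 h. With limma 0 of 17403 genes had an adjusted p under 0.05 at either time, and 574 and 793 genes (3.30% and 4.56%) had an unadjusted p under 0.05. The voom fit on recovered reads also called 0 genes at both times. The 84 genes that rose at 6 h had median changes of -0.13 (log2) at 24 h and -0.00028 at 48 h. The 225 genes that fell at 12 h lay at medians of -0.37 and -0.49, with 84.0% and 89.3% of them below 0 h, and took 4.14% ± 1.52 of all reads at 24 h and 3.42% ± 0.11 at 48 h (SD, n = 2). These genes were chosen against the same 0 h libraries, which by itself moves such medians away from 0. The median of all tested genes was -0.15 at 24 h and -0.02 at 48 h. JCGZ_24966 was the named gene farthest from its 0 h level at 48 h, at 61.7 ± 8.0 RPKM against 297 ± 125, a change of -2.19 ± 0.68 (log2, SE) with a limma adjusted p of 0.954.

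**Figure D4:**
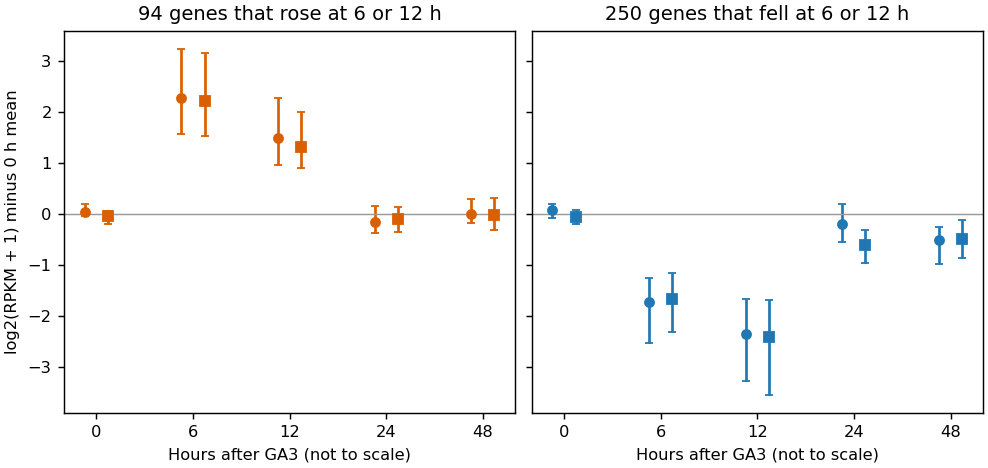
Median log2(RPKM + 1) relative to the mean of the 0 h libraries, with bars for the interquartile range over genes, for the 94 genes that rose (left) and the 250 that fell (right) at 6 or 12 h. Each point is 1 library (circles, number 1; squares, number 2) and hours are not to scale. The rising genes peak at 6 h with medians of 2.27 and 2.21, and the falling genes are lowest at 12 h with medians of -2.36 and -2.42. Of these genes, 84 of the rising ones were called at 6 h and 225 of the falling ones at 12 h, which by itself favours these times. The 113 genes that fell at 6 h had median changes of -2.23 at 6 h and -2.18 at 12 h. The 42 that rose at 12 h had medians of 2.52 at 6 h and 2.13 at 12 h.

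In comparisons between treated times the fold changes do not contain the 0 h libraries, although these enter the shared estimate of the spread and so affect which genes are called. From 12 h to 24 h, 148 genes rose and 53 fell (limma, adjusted p under 0.05), and from 6 h to 48 h, 53 rose and 93 fell. Of the 225 genes that had fallen at 12 h, 135 rose again from 12 h to 24 h, and of the 42 that had risen, 36 fell. Of the 113 and 84 genes that had fallen or risen at 6 h, 45 and 69 were called in the opposite direction from 6 h to 48 h. Each of these pairs of tests shares the 12 h or the 6 h libraries, which by itself favours opposite directions. Independent lists, which leave that out, would share 1.91 or fewer genes, and simulated unchanged groups, in which hardly any gene is called, shared at most 1, so neither value bounds the reversals expected among called genes. From 6 h to 12 h, 21 genes fell and 1 rose. From 24 h to 48 h, limma called 0 genes, 329 genes (1.89%) had an unadjusted p under 0.05, and voom called 0.

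The library numbers paired the treated libraries, and a replicate block among these 8 libraries raised the counts. With the block, 504 genes rose and 741 fell from 12 h to 24 h, 358 rose and 461 fell from 6 h to 48 h, 51 rose and 97 fell from 6 h to 12 h, and 0 changed from 24 h to 48 h. All 201, 146 and 22 genes called without the block remained. The median of all genes shifted by -0.22 (log2) from 12 h to 24 h, and with the block plus a correction for coding length 511 genes rose and 303 fell in that comparison, so which direction held more genes from 12 h to 24 h turned with these settings. Fitted on the 4 libraries of the pair alone, the comparison of 24 h with 12 h and that of 12 h with 6 h called 0 genes each, and that of 48 h with 6 h called 87. Leaving out single libraries gave 45 to 149 genes from 12 h to 24 h, lowest without 24 h library 1 (45), 12 h library 2 (53) and 12 h library 1 (66). The others that lowered it by over 1.5 times were either 0 h library (76 each), 6 h library 1 or 2 (113 and 114) and either 48 h library (126 each). From 6 h to 48 h the counts were 33 and 45 without 48 h library 2 or 1, 34 and 41 without 6 h library 1 or 2, and 64 without either 0 h library. From 6 h to 12 h they were 2 and 1 without 6 h library 1 or 2, 12 and 3 without 12 h library 1 or 2, 4 without either 0 h library and 9 without either 48 h library.

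Over the whole course, 230 genes changed at some time (limma F-test, adjusted p under 0.05), and 1807 had an unadjusted p under 0.05. For 228 of the 230, the fitted change from 0 h was largest at 6 h or 12 h. The largest group, 114 genes, was lowest at 12 h. In 71 genes the largest change was an increase at 6 h, in 33 a decrease at 6 h and in 10 an increase at 12 h. The remaining 2 genes had their largest change at 24 h (1, lower) and 48 h (1, higher). The count was 87 without either 0 h library, 90 and 91 without 6 h library 1 or 2, 126 and 131 without 12 h library 1 or 2, and 135 and 127 without 48 h library 1 or 2.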

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

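Chosen after their results had been seen were the tests of the coding length trend, of depth, of crossed numbers and of a batch, the splits by library number and by whole times, and the positions in the fit to the treated libraries alone.

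These results stand out as differences between the changes at 2 times, tested as such. The change from 0 h differed between 12 h and 24 h in 201 genes, between 6 h and 48 h in 146 genes and between 6 h and 12 h in 22 genes (limma, adjusted p under 0.05). All 8 named genes differed between 12 h and 24 h, but they had been chosen for large changes at 6 h or 12 h. The 12 h libraries enter both comparisons, which by itself favours such reversals. Fitted on the 4 libraries of 12 h and 24 h alone, limma called 0 genes (smallest limma adjusted p = 0.0531). From 12 h to 24 h, JCGZ_08534, JCGZ_01274, JCGZ_26846 and JCGZ_10281 changed by -4.92, -2.88, -4.70 and -4.77 (log2). JCGZ_14173, JCGZ_24966, JCGZ_02232 and JCGZ_02380 changed by 4.87, 3.89, 8.50 and 6.80.

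The first pattern is that genes changed at 6 h and 12 h while limma called 0 at 24 h and 48 h (574 and 793 with an unadjusted p under 0.05, and 0 by voom). A larger spread at the later times is argued against by the standard deviation of the replicate difference. It was 0.70 at 6 h, 0.75 at 12 h, 0.76 at 24 h and 0.75 at 48 h, and all comparisons shared 1 estimate of the spread. The 0 h level of the 201 genes called between 12 h and 24 h lay at a median of -0.020 between the 24 h level (0) and the 12 h level (1). For the 1245 genes called from the 8 treated libraries alone the median was 0.17 (-0.046 for the 504 that rose and 0.32 for the 741 that fell). With 0 genes called at 24 h against 0 h, positions nearer the 24 h level were largely fixed in advance, so they do not bear on the spread. The coding length trend is argued against by 429 genes called at 12 h after its correction. A daily rhythm may account for the pattern, because 0, 24 and 48 h fall at the same hour of the day if all plants were treated together. The 48 h level lay at a median of 0.10 for the 201 genes and 0.29 for the 1245 (0.13 for those that rose, and 0.45 with quartiles of 0.21 and 0.71 for those that fell), but a response to GA3 that ends by 24 h can give such values too, so without untreated plants at the later times the treatment and time of day cannot be told apart. The grouping of 6 and 12 h against the rest, itself chosen after the library map had been seen, called 941 genes. The other splits among 100 drawn from 210 called at most 8. The 210 also hold a split that was not drawn, the treated libraries of number 1 against all others. That split called 3275 genes, so 941 was not the highest count among the 210. The other drawn splits also part the libraries of a time. The 10 splits that keep times whole (highest other 0) are too few for a share under 0.05.

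The second pattern is that treated libraries of the same number deviate together: setting the 4 of number 1 against the other 6 libraries called 3275 genes, several times the 941, which points to a structure of the samples. Depth is argued against, because number 1 was deeper at 2 of the 4 treated times, and the coding length trend is argued against as the whole cause, because the mean correlation of the replicate differences was 0.63 before and 0.56 after its correction. A batch marked by the numbers as given at all 5 times is argued against, because the 0 h difference correlated with the treated times at -0.32 to -0.14. Numbers crossed at 0 h stay open, since these correlations are negative, and -0.20 to -0.046 after the length correction, but weaker than the 0.54 to 0.70 among the treated times. Separate plants, or a handling that differed within the treated times alone, stay open and were not tested, since the labels describe neither.

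The third pattern is that more genes fell than rose at 12 h. Scaling is argued against, because 85.3% and 86.6% of the calls were falls under median-of-ratios and upper-quartile scaling, and the length trend is argued against by 80.2% after the correction. The share was lower in some other alternatives and lay between 69.3% (80 rose, 181 fell, in a fit to 4 libraries) and 92.5% over the 24 run. A response to GA3, which the design names, and time of day stay open and untested.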

How the results depend on the processing

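The fits with voom, library weights, the coding length correction and the block among treated libraries were chosen after seeing the data. The counts of 0 genes at 24 h and 48 h against 0 h and at 48 h against 24 h held in every alternative run, and none of the named genes changed direction. The 8 named genes were chosen by these same calls, and some settings, such as the 2-fold minimum, could not drop them. How often they passed again is therefore weak support. The calls of JCGZ_24966, JCGZ_10281 and JCGZ_08534 were lost without some libraries of their own comparison. With all libraries kept, voom also lost JCGZ_24966 (voom adjusted p = 0.0507) and JCGZ_10281 (voom adjusted p = 0.0783). The 2-fold minimum could change no count, because every called gene had changed at least 2-fold. Scaling, pseudocount, non-robust moderation and a mean of at least 5 RPKM left the other counts within 1.5 times, except 9 genes for 12 h against 6 h under median-of-ratios scaling. Without a filter that comparison gave 14 genes and 24 h against 12 h gave 131. The library numbers do not pair the 0 h libraries with the others (correlations of -0.32 to -0.14). No alternative therefore took the difference between numbers properly out of a comparison with 0 h. The counts of 0 genes at 24 h and 48 h against 0 h thus do not show that no gene changed. The replicate block over all 10 libraries, in the order 6 h and 12 h against 0 h, 12 h against 6 h, 24 h against 12 h and 48 h against 6 h, gave 351, 526, 55, 321 and 286 genes, 430 over any time and an overlap of 220. The coding length correction gave 324, 429 and 309 genes for 6 h and 12 h against 0 h and 24 h against 12 h, and an overlap of 185, and with the replicate block 559, 727, 65, 484 and 391 in the order above, 567 over any time and an overlap of 330. The block among the 8 treated libraries gave 148, 1245 and 819 genes for 12 h against 6 h, 24 h against 12 h and 48 h against 6 h, and with the length correction 137, 814 and 777. Fits to 4 libraries gave 427 genes for 6 h against 0 h, 0 for 12 h against 6 h, 0 for 24 h against 12 h and 87 for 48 h against 6 h. Library weights gave 473 genes for 6 h against 0 h, 99 for 24 h against 12 h, 356 over any time and an overlap of 209. Voom gave 12 genes for 12 h against 6 h, 1.2e+02 (90 rose and 33 fell) for 24 h against 12 h and an overlap of 76. Leaving out 1 library gave 17 to 190 and 35 to 302 genes for 6 h and 12 h against 0 h, 1 to 26, 45 to 149 and 33 to 129 for the 3 comparisons between treated times, 87 to 214 over any time and an overlap of 8 to 119, and the lone library was then assumed to vary like the other groups. Why the counts moved was otherwise not tested. With 2 libraries per time the simulated test at 12 h called 0 of 100 genes changed 2-fold, and sizes between 2-fold and 4-fold and the blocked fits were not simulated. The planned count-based packages and the 30 gene lists were not run, for the reasons given with the processing.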

Other observations

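The test of abundance was chosen after the result on IDs without a locus tag had been seen, and the reading of that result was revised after it; the tests of consecutive tags and of the share changed were set before their results. Among the 218 JCGZ genes that fell at 12 h, 12 had a consecutive locus tag number that also fell, against a mean of 4.32 in random draws of as many tested genes (one-sided permutation test with 100000 resamples, p = 0.02). If consecutive numbers mark neighbouring genes, which was not checked here, neighbours may share regulation, and near-identical copies that share reads would give the same result. Of 919 tested genes without a locus tag, 4 (0.435%) changed over the time course, against 226 of 16484 JCGZ genes (1.37%; odds ratio 0.314, 95% interval 0.0848 to 0.819, two-sided Fisher's exact p = 0.0109). Those without a tag were less abundant (median 5.78 against 20.6 RPKM), and 9.58% of 10000 draws of JCGZ genes matched on mean RPKM had as few changed genes, with a mean of 7.96, so lower abundance may account for the difference.

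Reads fell on shorter genes in some libraries than in others. The mean gene length per read was 1298 and 1165 bases at 0 h, 1150 and 1258 at 6 h, 1112 and 1455 at 12 h, 1039 and 1263 at 24 h, and 1191 and 1466 at 48 h, for libraries 1 and 2. The sum of RPKM over genes ranged from 1073141 (48 h, library 2) to 1442733 (24 h, library 1).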
